A study of Drosophila yakuba and Drosophila melanogaster with 20 samples.

How the data were processed

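Total RNA (5 µg) was taken from about 50 fly heads per sample, selected with oligo(dT), fragmented, and incubated with 1.6 M acrylonitrile or without it (mock) at 70 °C for 1 h, per the labels' protocols. Reads were mapped to the BDGP R5 assembly (dm3) for D. melanogaster or to WUGSC 7.1 (droYak2) for D. yakuba with TopHat 2.0.6 and Bowtie 2.0.2, allowing 4 mismatches and keeping 1 alignment per read, and unmapped reads were remapped with bsmap 2.74 allowing 3 mismatches, per the labels' protocols. SAMtools 0.1.19 is named in the submitters' processing notes. How base differences were called, with which minimum of depth, base quality or level, is not given in the sources used here, nor is the rule by which sites were called from ICE and mock libraries. In the TopHat step the mismatch allowance limits how many edited bases a read can carry. The protocol's bsmap command carried a further option, -M, beside the mismatch limit. Whether that option let A-to-G differences through beyond the limit was not examined. Whether the bsmap step recovered reads of densely edited transcripts was not examined either, so these can be under-represented. Keeping 1 alignment per read leaves open where reads of repeated sequence came from, including those on heterochromatin scaffolds.

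The deposited site lists give 1-bp positions, one list per species, with no strand, score, gene name or editing level. The deposited tables of the 4 HiSeq and NextSeq mock libraries give chromosome, position, reference base and differing base, per the file headers. They hold no read counts or depth. The differing base is in upper or lower case, read here as forward and reverse read strand, as in a SAMtools pileup; the files do not state this.

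These contents changed the plan made before the data were examined. Editing levels, their reproducibility between replicates, the test of levels between instruments with edgeR, minimum read numbers, the removal of differences at high level, the selection of sites by score, and expression differences need counts, levels or scores, and were not computed. The lists name no genes and no annotation of dm3 or droYak2 was used here, so tests of gene groups, the overlap of edited genes between species, and the location of sites in transcripts were not run. The rule for named items, set before the data were examined, was the 10 genes with the most sites per species or, without gene names, the 5 regions with the most sites, ties by position. The gap of 10000 bp that bounds a region was chosen after the data were seen. The group with the most sites at gaps of at most 100 bp, given for each species, was chosen afterwards.

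A difference was a distinct position and base within a library. The edited strand was taken from the reference base in the library tables, A for the forward and T for the reverse strand, and is known only at detected sites. A listed site was detected when the library listed A-to-G or T-to-C there. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Species were compared by permuting 10000-bp regions between lists (100000 permutations, two-sided); single and grouped sites were compared the same way over groups at 100 bp. Platform means were compared by exact permutation of the 4 libraries, which cannot go below p = 0.333. Paired detection was compared by exact McNemar tests, and neighbouring bases by Fisher's exact tests, which treat sites as independent. Adjusted p-values are Benjamini-Hochberg. Bases next to sites were read from the reference column of the tables, leaving out A-to-G and T-to-C entries so that editing itself does not choose the bases, and compared with offsets 3 to 10. With no read counts, the number of differences per library (117717, 201736, 423039 and 1097716 lines) is not a depth, and a site missing from a library cannot be separated into uncovered and unedited.

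Shared spacing between species was searched as chains of 3 or more sites, over 20 bp or more and with gaps of at most 1000 bp, that had identical distances in both lists in either orientation. The number was set against 1000 shuffles of the D. yakuba gaps. No coordinates were converted between genomes.

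The steps were tested on simulated data. Of 20 spacings planted in a shuffled D. yakuba list and searched with the 1238 D. melanogaster sites, 20 were recovered. In 1000 simulated sites the depleted 5' base was found and 0 of 4 tests on the 3' side passed. The region permutation gave p under 0.05 in 6 of 100 draws of 300 regions without a difference and found the planted difference. The strand assignment recovered 199 of 199 placed differences. The planted spacings were exact copies, and the placed differences lay close to their sites. No simulation used as few known neighbouring bases as the data gave. These checks therefore test the steps, not their power in the data.

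The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives fixed before the data were examined and computed were merging sites closer than 100 bp, keeping differences or sites found in both replicates of an instrument, and leaving out each replicate. Region sizes, leaving out heterochromatin scaffolds, both-strand filters, the replicate block on the composition and on detection, the neighbouring-base settings, the strand comparisons, the comparisons of spacing and of close sites, the search of unlisted differences and the shared spacing were chosen after the data were seen.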

Results

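The series profiled A-to-I RNA editing in adult heads of Drosophila melanogaster and its relative Drosophila yakuba. Adenosine deaminases acting on RNA convert adenosine to inosine, which is read as guanosine, so that an edited base appears as an A-to-G difference from the genome, or as T-to-C when the transcript comes from the reverse strand. ICE-seq (inosine chemical erasing) treats RNA with acrylonitrile, which modifies inosine and stops reverse transcription there. Comparison with a mock-treated library then separates inosine from other sources of A-to-G differences. The labels describe 20 libraries. For D. yakuba there were 6 ICE libraries and 6 mock libraries from 6 strains. For D. melanogaster there were 2 ICE libraries, 2 mock libraries, and 2 mock libraries each under the names of the HiSeq (50-nt reads) and NextSeq (86-nt reads) instruments.

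The values analysed here were the authors' list of editing sites for each species and the tables of base differences of the 4 HiSeq and NextSeq libraries; the other 16 libraries enter only through the site lists. Each table gives positions at which a read base differed from the dm3 genome, without read counts, so that sequencing depth and the editing level of a site are unknown. The number of differences, counting each position and base once, was 115079 and 196988 in HiSeq replicates 1 and 2, and 419113 and 1087962 in NextSeq replicates 1 and 2. The labels do not say that the replicates came from separate groups of flies.

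Listed editing sites were similar in number in the 2 species and occurred in dense groups in both. The D. melanogaster list held 1238 sites and the D. yakuba list 1250. In D. melanogaster 691 sites (55.8%, exact 95% binomial interval 53.0 to 58.6) had another listed site within 100 bp, against 620 sites (49.6%, 46.8 to 52.4) in D. yakuba. Directly adjacent bases made up 122 of the gaps between neighbouring sites in D. melanogaster and 92 in D. yakuba, and the median gap was 832 bp and 1752 bp. When sites with gaps of at most 100 bp were joined, the lists formed 785 and 865 groups, of which 547 and 630 held a single site and the largest held 8 sites in each species.

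Close spacing was more frequent in D. melanogaster. Sites with a neighbour within 10 bp were 39.4% of the D. melanogaster list and 30.1% of the D. yakuba list, a difference of 9.34 percentage points (two-sided permutation test over 419 and 493 regions joined at gaps of at most 10000 bp, p = 0.0016, Benjamini-Hochberg adjusted p = 0.0065 over 4 shares compared). The difference within 100 bp, 6.22 points, did not pass the permutation test (p = 0.0718, adjusted p = 0.144), although it did with regions joined at 1000 bp (unadjusted p = 0.0449) or at 100 bp (p = 0.0312). The labels give 6 strains for one species and 2 replicates for the other, and neither the libraries behind each list nor the calling rule is given in the sources used here, so these tests compare the lists.

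**Figure D1:**
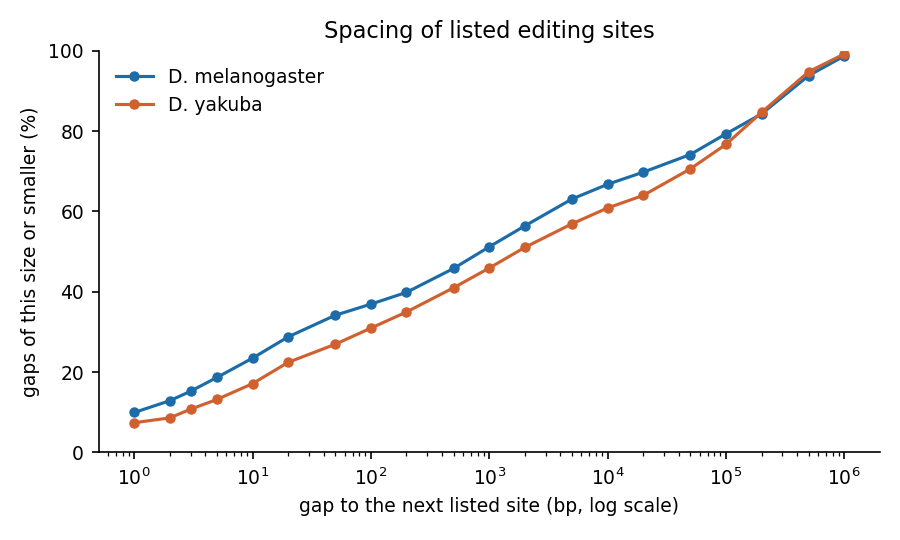
Cumulative share of gaps between neighbouring listed sites (vertical axis, percent of gaps) against gap size (horizontal axis, bp, log scale) for the D. melanogaster and D. yakuba lists. Gaps of at most 10 bp were 23.5% of the gaps in D. melanogaster and 17.1% in D. yakuba.

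The X chromosome carried more listed sites than any other chromosome arm in both species. It held 412 sites (33.3%, 30.7 to 36.0) in D. melanogaster and 334 (26.7%, 24.3 to 29.3) in D. yakuba, while the small chromosome 4 held 32 and 35 sites. Another 32 D. melanogaster sites lay on heterochromatin scaffolds. The X share was 6.56 points higher in D. melanogaster, a difference that did not pass the permutation test over 10000-bp regions (p = 0.271, adjusted p = 0.362). It passed when regions were joined at 100 bp (permutation p = 0.0186). Counted as regions, X held 99 of 419 in D. melanogaster and 96 of 493 in D. yakuba (Fisher's exact test, two-sided, p = 0.145). The share of chromosome 4 differed by -0.215 points (permutation p = 0.881, adjusted p = 0.881).

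The richest regions were tracts of 14031 to 37377 bp in D. melanogaster, and 4 of the 5 lay on X. The region with the most sites, at X from 17820657 to 17858033 (dm3), held 33 sites, of which 29 had an A-to-G or T-to-C difference in at least 1 of the 4 mock libraries. The region at X from 16354271 to 16376726 held 28 sites, and 25 of these were listed in all 4 libraries. None of the 26 sites at X from 17871687 to 17885717 was listed in all 4 libraries: 22 were listed in HiSeq replicate 2 and 17 in NextSeq replicate 2, but only 1 in each library of replicate 1. The remaining regions held 23 sites each, at 2L from 14077162 to 14091478, with 11 sites in all 4 libraries, and at X from 11843915 to 11871571, with 8. Wherever the edited base was known in these regions it was T throughout the 4 regions on X and A throughout the region on 2L.

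In D. yakuba the richest region, at X from 10472025 to 10497694 (droYak2), held 39 sites. It was followed by 30 sites at 2L from 12487576 to 12511405, 26 sites at X from 16439292 to 16462756, 24 sites at X from 14830066 to 14866512, and 21 sites at 2L from 14171090 to 14188327. The groups with the most sites at gaps of at most 100 bp were 8 sites within 83 bp at 2L from 13487538 to 13487620 in D. melanogaster and 8 sites within 114 bp at X from 12395981 to 12396094 in D. yakuba. Genes and transcript parts at these positions were not annotated here.

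**Figure D2:**
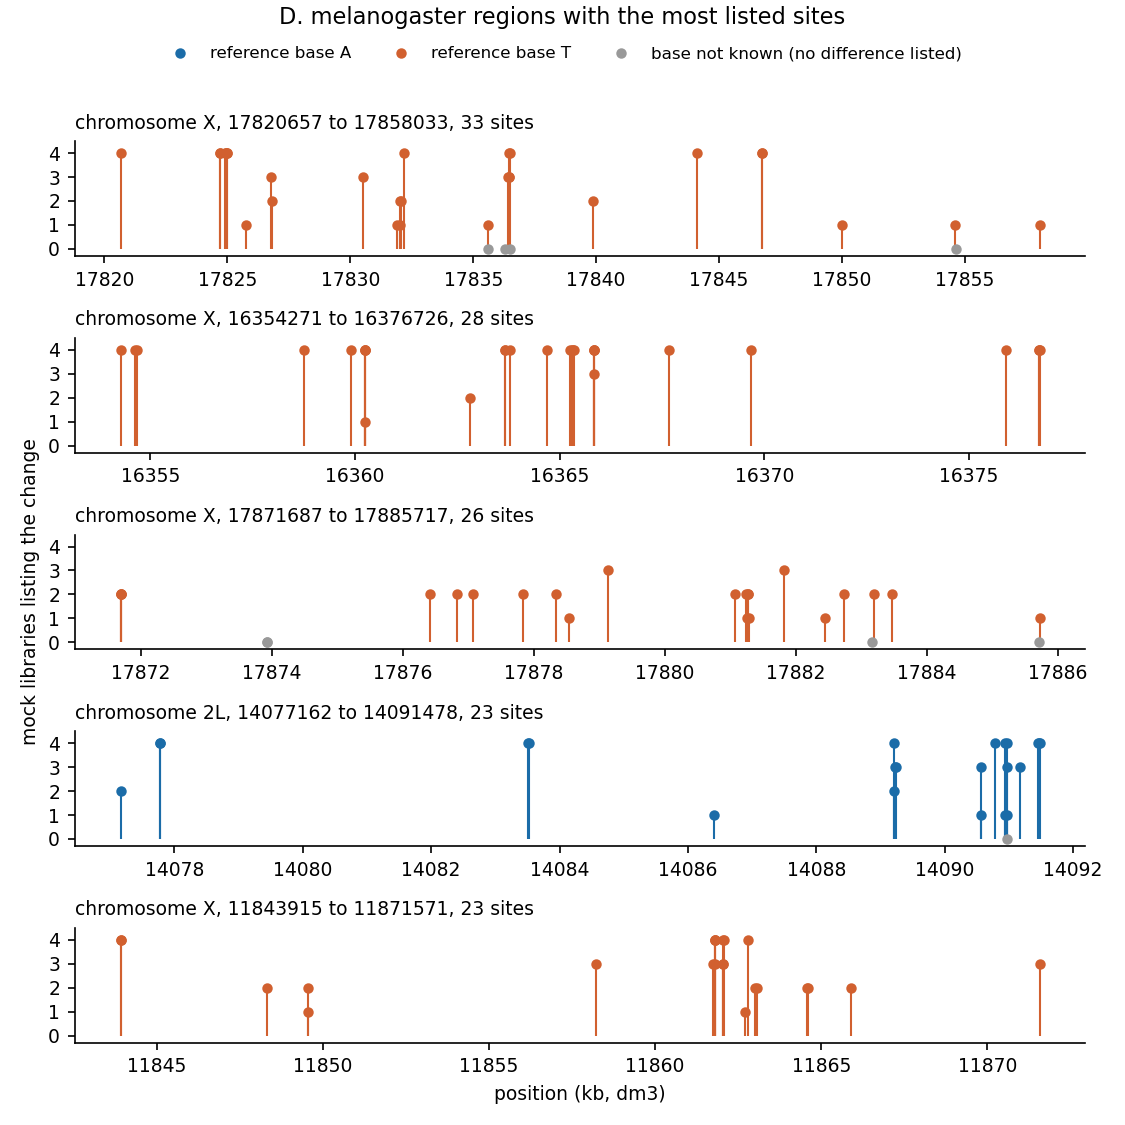
The 5 D. melanogaster regions with the most listed sites, with position on the dm3 chromosome (horizontal axis, kb) and the number of the 4 mock libraries that listed A-to-G or T-to-C at each site (vertical axis); colour gives the reference base. Within each region every site of known base has the same base, and the region starting at 16354271 on X has 25 of its 28 sites in all 4 libraries.

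Most D. melanogaster sites of the list were visible in mock-treated RNA sequenced on HiSeq or NextSeq. An A-to-G or T-to-C difference was found at 1084 sites (87.6%, 85.6 to 89.3) in at least 1 library and at 362 sites (29.2%, 26.7 to 31.9) in all 4, while 154 sites had none. The reference base was A at 607 of the detected sites and T at 477. Other base changes were rare at listed positions: 90 were found, and 2 of these recurred in 2 or more libraries. HiSeq replicates 1 and 2 listed 556 (44.9%) and 944 (76.3%) of the sites, and NextSeq replicates 1 and 2 listed 502 (40.5%) and 891 (72.0%). Whether these tables contributed to the site list is not stated.

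Sites that belonged to groups were detected more consistently than isolated sites. Of the sites with a neighbour within 100 bp, 35.0% were listed in all 4 libraries, against 21.9% of single sites, a difference of 13.1 points (permutation test over 238 groups and 547 single sites, two-sided, p = 1.6e-04, adjusted p = 3.2e-04 over 2 comparisons). For detection in any library the shares were 89.9% and 84.6% (permutation p = 0.0270, adjusted p = 0.0270). Groups and single sites within the same 10000-bp region are not independent. No test over 10000-bp regions was run here, so these p-values may be too small. Expression of the transcripts was not measured, so detection was not set against depth.

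Detection varied more between replicate numbers than between instruments. The mean share of sites detected was 60.6% ± 22.2 (SD, n = 2) on HiSeq and 56.3% ± 22.2 (SD, n = 2) on NextSeq (exact permutation test, two-sided, p = 0.667; the smallest p possible with 2 against 2 libraries is 0.333). Within numbers, NextSeq minus HiSeq was -4.36 points for replicate 1 and -4.28 points for replicate 2, and 2 pairs cannot give an exact two-sided p below 0.5. Site by site, HiSeq replicate 1 listed 153 sites that NextSeq replicate 1 did not, and the reverse held for 99 (exact McNemar test, two-sided, p = 8.08e-04, adjusted p = 0.0012). For replicate 2 the numbers were 157 and 104 (exact p = 0.0012, adjusted p = 0.0012). Drawing 1 site per 10000-bp region reduces the dependence among neighbouring sites, though regions close to each other may still be dependent. The numbers were then 49 and 34 for replicate 1 (exact McNemar p = 0.124) and 60 and 44 for replicate 2 (p = 0.141).

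Listed sites stood apart from other A-to-G and T-to-C differences in their recurrence and in how often both read strands showed them. Of such differences found in a single library, 0.173% were on the site list. The share rose to 3.49% of those in 2 libraries, 20.5% of those in 3 and 52.8% (362 of 685) of those in all 4. Of the 161 seen on both read strands in all 4 libraries, 117 (72.7%, 65.1 to 79.4) were listed sites. In single libraries, 38.3% to 58.0% of detected listed sites were seen on both read strands, against 1.07% to 1.59% of unlisted A-to-G and T-to-C differences. Read strand was taken from the letter case of the base, which the files do not define. The calling rule of the list is not given in the sources used here. If it used recurrence or both read strands, these contrasts would follow from it.

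Neighbouring listed sites were edited on the same strand. For all 551 neighbouring pairs at most 1000 bp apart in which both bases were known, the reference base was the same, A with A or T with T. Random reassignment of the bases among sites gave at most 326 such pairs (59.2%; permutation test, one-sided, p = 1e-05, the smallest value the permutations can give). The reassignment ignored which sites lie close together. It tests only whether strand is independent of position, which would fail for any positions within the same transcript. Between 1000 and 10000 bp, 166 of 170 pairs (97.6%, 94.1 to 99.4) had the same base, and beyond that distance 187 of 352 pairs (53.1%, 47.8 to 58.4) did. Of 174 regions with at least 2 sites of known base, 171 held only one of the bases.

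The base 5' of listed sites was rarely G. Where the tables showed the reference base next to a site, through a difference other than A-to-G or T-to-C, G stood at 3 of 76 positions on the 5' side (3.95%, 0.822 to 11.1), against 15.8% at 3 to 10 bases on either side (Fisher's exact test, two-sided, p = 0.0029, adjusted p = 0.0233 over 8 tests). On the 3' side G made up 22.1% of 104 known bases (exact p = 0.0999, adjusted p = 0.167). At unlisted A-to-G and T-to-C differences more than 10000 bp from any listed site and found in 2 or more libraries, G was more frequent on the 5' side, 25.1% of 1206 known bases against 18.1% around them (exact p = 6.09e-09). Deaminases of this family are known to disfavour a 5' G. The difference at listed sites did not pass Fisher's exact test in the HiSeq tables alone (0 of 9 bases, exact upper limit 33.6%, p = 0.118) or without replicate 2 (0 of 21, upper limit 16.1%, p = 0.059), and neighbouring sites are not independent.

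**Figure D3:**
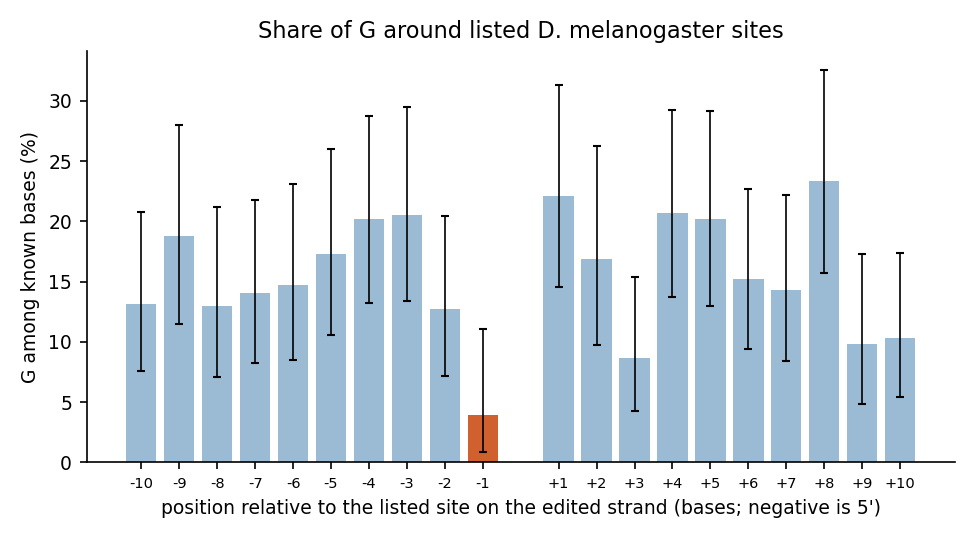
Share of G among known reference bases (vertical axis, percent) at each position from 10 bases 5' to 10 bases 3' of listed D. melanogaster sites on the edited strand (horizontal axis); bars give the share and lines the exact 95% binomial interval. The position directly 5' of the site, at 3.95%, is the lowest.

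The kinds of base change differed between HiSeq and NextSeq libraries. Read length differed as well, 50 nt on HiSeq and 86 nt on NextSeq, and depth is unknown. An effect of the instrument therefore cannot be told apart from these, in the base changes or in detection. A-to-G and T-to-C together made up 21.1% ± 1.16 (SD, n = 2) of the differences on HiSeq and 5.39% ± 0.666 (SD, n = 2) on NextSeq, a difference of -15.7 points (exact permutation test, two-sided, p = 0.333, the smallest possible). The lower share came with more differences of other kinds: A-to-G and T-to-C numbered 23305 and 43130 in the HiSeq libraries and 24545 and 53467 in the NextSeq libraries, while all differences were 4.83 times as many on NextSeq. On HiSeq the 12 kinds of change lay between 4.76% and 11.1% of differences. On NextSeq A-to-T and T-to-A made up 25.7% each, and C-to-A and G-to-T 12.1% and 12.0%. In the sense of the read, as given by letter case, T-to-A was 41.7% ± 1.01 (SD, n = 2) of NextSeq entries and C-to-A 22.2% ± 1.82 (SD, n = 2), while the reverse complements A-to-T and G-to-T were 9.72% and 1.92%. Among differences seen on both read strands, A-to-G and T-to-C made up 21.7% on HiSeq and 11.5% on NextSeq.

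**Figure D4:**
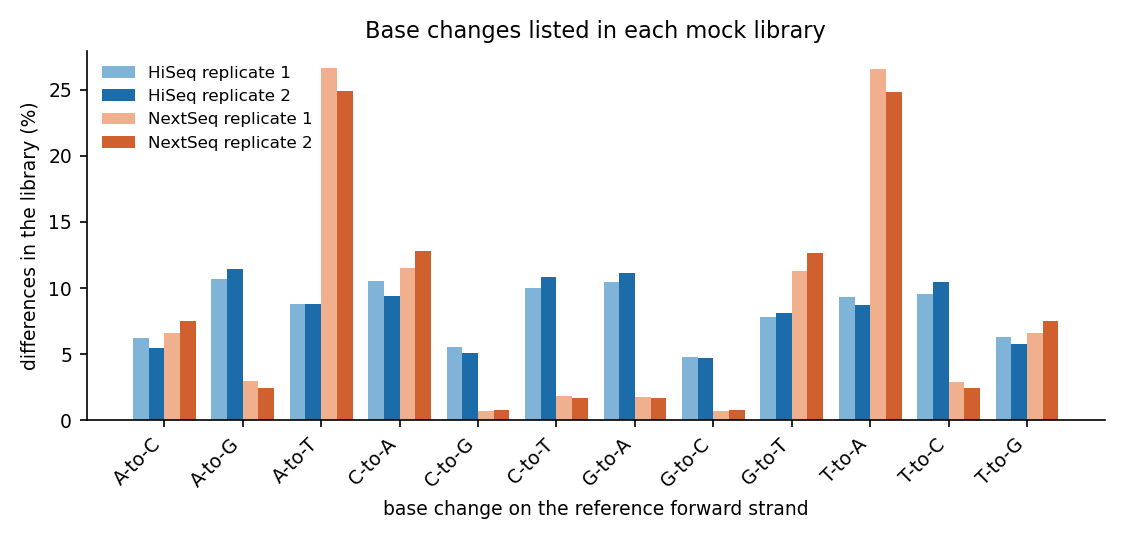
Percentage of differences (vertical axis) for each of the 12 base changes on the reference forward strand (horizontal axis) in the 4 mock libraries, 1 bar per library. A-to-T and T-to-A reach 24.8% to 26.6% in the NextSeq libraries and 8.76% to 9.32% in the HiSeq libraries.

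Replicates shared listed sites far more often than other differences. How the list was called is not given, so recurrence may have been part of the rule. HiSeq replicates 1 and 2 shared 505 listed sites, 90.8% of those in the smaller set, but 5.61% of unlisted A-to-G and T-to-C differences. NextSeq replicates 1 and 2 shared 450 listed sites (89.6%) and 5.01% of the unlisted differences. Libraries of the same number on the 2 instruments shared more unlisted differences than the replicates of one instrument, 13.9% for number 1 and 11.5% for number 2. At listed sites they shared no more than the replicates by this measure, 80.3% for number 1 and 88.3% for number 2. Of the listed sites found in either library, however, they shared 61.5% for number 1 and 75.1% for number 2. The replicates shared 50.8% on HiSeq and 47.7% on NextSeq by that second measure, so the comparison at listed sites depends on the measure. The series' design text can be read as the same additional libraries run on both instruments, in which case the 4 tables come from 2 library preparations.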

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

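The tests on unlisted differences were chosen after their counts had been seen, except the test of the 5' base, which was set before its result.

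A signal appeared at positions outside the site list. Within 100 bp of a listed D. melanogaster site, 587 unlisted positions showed A-to-G on the strand of that site in 2 or more libraries, against 31 on the opposite strand. Among unlisted differences in 2 or more libraries, those of this kind made up 74.3% (69.6 to 78.7, exact 95% interval) at 10 bp or less from a listed site, 22.1% between 50 and 100 bp, and 5.73% beyond 10000 bp, where the opposite strand gave 4.93%. Requiring at least 1 library of each replicate number left 309 positions against 6 on the opposite strand, and all 4 libraries listed 68 against 1. The count was 374 against 17 without replicate 1 and 165 against 12 without replicate 2.

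Sequencing or mapping error without a strand preference would give both strands alike at well covered positions. The ratio of same-strand to opposite-strand counts was 18.9, falling to 4.28 when 1 library sufficed and to 8.29 within 500 bp. Strain variants would give G-to-A about as often as A-to-G, and the ratio was 14.3, falling to 5.66 and 6.10 under the same settings. Misplaced reads that carry A-to-G on 1 strand would pass both ratios, and mapping error of that kind was not tested. Editing at positions left off the list is a candidate explanation, for which the base 5' of these positions was read: G made up 7.14% of 98 known bases, against 12.6% around them (Fisher's exact test, two-sided, p = 0.148). The bound set beforehand, p above 0.05, was met, but the interval of 2.92% to 14.2% holds both the surrounding share and the 3.95% at listed sites, so too few bases were known for that bound to decide and the explanation stays open. Errors made evenly along the RNA strand during reverse transcription would not depend on the distance to a listed site. In 2 or more libraries the same-strand share fell from 74.3% at 10 bp or less to 22.1% between 50 and 100 bp. That fall argues against such even errors for these positions. Errors that do depend on this distance were not tested. The design's comparison of ICE with mock libraries, which bears on editing at these positions, was not used here because the tables analysed come from mock libraries only.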

How the results depend on the processing

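Merging sites, keeping differences or sites in both replicates, and leaving out each replicate were chosen before the data were examined, except for the instrument differences, the 5' base and the unlisted positions; the other settings, and every test named here, were chosen afterwards. Of 56 alternative values, 31 kept their side of the threshold or, untested, lay within 1 SD of the replicates or 1.5 times a count. These bounds are wide: either of 2 libraries lies within 1 SD of their mean, so leaving 1 out always passes. D. yakuba groups at 100 bp (866 from 1250 sites) and instrument tests with a replicate block, which cannot pass, count as kept. No difference changed direction, but region size and the block cannot change one. The causes of the changes below were not tested, except where fewer sites or libraries entered by construction.

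Merging sites closer than 100 bp left 787 D. melanogaster groups; merging at 1000 bp and 10000 bp left 610 and 419 in D. melanogaster and 679 and 493 in D. yakuba. The share of A-to-G and T-to-C was 19.2% on HiSeq and 4.31% on NextSeq among differences in both replicates, and 11.5% on NextSeq among those on both strands. Detection was 44.9% to 76.3% on HiSeq and 40.5% to 72.0% on NextSeq when a replicate was left out, and 40.8% and 36.3% in both replicates, all within 1 SD. Detection on both strands was 30.2% of sites on HiSeq and 28.8% on NextSeq. The X difference of 6.56 points passed with regions at 100 bp (permutation p = 0.0186); the difference in neighbours within 100 bp, 6.22 points, passed at 100 bp (p = 0.0312) and 1000 bp (p = 0.0449), and that within 10 bp passed throughout (p from 7.6e-04 to 0.0031). The 5' G share was 0% in the HiSeq tables alone (exact p = 0.118) and 0% to 5.36% when a replicate was left out, with p = 0.059 without replicate 2, where fewer bases were known. Unlisted positions numbered 2039 in 1 or more libraries (476 on the opposite strand), 68 in all 4 (1), 309 in both replicate numbers (6), 281 within 10 bp (6), 945 within 500 bp (114), and 165 to 374 when a replicate was left out (12 to 17). Shared chains numbered 57 at 3 or more sites (permutation p = 0.125) and 42 at a span of 50 bp or more (p = 0.0569), neither past the threshold, and passed at 4 or more (20, p = 0.001), at 4 or more with each D. yakuba tract used once (18, p = 0.001) and at 4 or more over 50 bp (13, p = 0.001).

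With the replicate number as a replicate block, NextSeq minus HiSeq stayed at -15.7 points in the A-to-G and T-to-C share, with a standard error of 1.29 paired and 0.947 unpaired, and at -4.32 points in detection, with 0.0404 paired and 22.2 unpaired. The exact tests used here cannot pass with 2 libraries per instrument, with or without the block, so they made no call. The detection difference was 0.195 times its standard error unpaired and 107 times paired, so a test resting on these errors would depend on the block, while the composition difference was 16.6 and 12.1 times its error. Within-instrument detection differences correlated between instruments (r = 0.290 over 1238 sites, which are not independent). The labels do not say that the numbers pair the libraries; the sharing of differences by number is a hint from the data that they do. Without read counts, the minimum-read, level and score alternatives were not run, nor were those on gene groups, edited genes, editing levels and expression.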

Other observations

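All tests on shared spacing, the test of sharing by replicate number and the comparison of runs were chosen after the pattern had been seen; the test of letter case was set before its result, but its comparison with listed sites was added afterwards.

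Several tracts of D. melanogaster and D. yakuba sites had identical spacing. The longest chain was 7 sites at 3L from 2940919 to 2941426 (dm3), matched in inverted order by 3L from 8994427 to 8994934 (droYak2). Chains of 6 sites joined 3L from 4369162 to 4369445 with 3L from 4942987 to 4943270, and 2L from 13485127 to 13485162 with 2L from 9913295 to 9913330. These 3 chains are named because they are the longest, a choice made after seeing them.

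After an earlier look at pairs of consecutive gaps, the search was set at 3 or more sites, and 57 chains were found, no more than chance coincidence of short gaps gives (shuffled median 52, highest 64, p = 0.125), although 38.6% joined the same chromosome arm against 20.3% from the arm composition of the lists (exact binomial test, one-sided, p = 0.0011), which did not pass among the 42 chains over 50 bp or more (31.0%, exact p = 0.0677). The split by chain length was made after that result, among 6 settings in all: 20 chains had 4 or more sites (shuffled median 4, highest 14, p = 0.001, the smallest value the shuffles can give), and 80% of these joined the same arm (exact binomial, one-sided, p = 1.68e-08). Some of these share a D. yakuba tract and cannot all be homologous; with each tract used once, 18 chains remained (permutation p = 0.001, shuffled highest 9), 77.8% on the same arm (exact binomial, p = 2.6e-07). The 37 chains of exactly 3 sites were fewer than the shuffled median of 47 (permutation p = 0.991 for an excess). Of these, 16.2% joined the same arm (exact binomial p = 0.789). They showed no excess by either comparison, and conservation among them stays open. Why they were fewer than in the shuffles was not tested. Shuffling breaks up runs of short gaps and can understate chance among dense sites, which the comparison of arms does not depend on. For the chains of 4 or more sites, conserved positions in homologous sequence may account for the shared spacing, a hypothesis that an alignment of the genomes, not used here, would test.

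Differences were shared between the HiSeq and NextSeq library of the same number far more than between numbers. An equal depth profile in all 4 libraries would give an odds ratio near 1. The ratio bears only on that case. Depth or expression that differs between the replicate numbers could raise it too, and this was not tested. For changes other than A-to-G and T-to-C it was 17.7 (95% interval 16.7 to 18.8), with 8.93 for A-to-T and T-to-A and 118 for C-to-G and G-to-C. It was 76.4 (65.6 to 89.1) for unlisted A-to-G and T-to-C, and 13.2 (4.76 to 36.5) at listed sites. The value at listed sites rested on replicate 2, with 246 sites shared within replicate 2 and 9 within replicate 1. Another 14 and 12 listed sites were shared across numbers. Variants carried by the flies would appear on either read strand, yet for these other changes the letter case agreed in 86.3% of 23046 shared differences seen on a single strand in each library, against 63.1% of 5432 shared between numbers, above the 50% that had been assumed, and against 72.5% of 102 at listed sites of the same number (62.8 to 80.9; Fisher's exact test, two-sided, p = 2.34e-04). Copies of the same cDNA fragments sequenced on both instruments could give such agreement, and variants may still make up a part, but listed sites agreed in 68.8% of 16 between numbers (exact p = 0.769 against 72.5%), so nothing shows copies there and why they too were shared by number stays open. If the 4 tables represent 2 preparations, presence in all 4 is weaker evidence than 4 independent libraries would give.

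Unlisted A-to-G and T-to-C differences more than 1000 bp from any listed site also formed runs on a single strand. Among those in 3 or more libraries, 105 of 115 neighbouring pairs at most 100 bp apart had the same reference base (91.3%, 84.6 to 95.8), against 235 of 492 pairs (47.8%) more than 10000 bp apart. The largest run held 8 positions, between 9556 and 9599 of the mitochondrial genome, where other transitions recurred as often in all 4 libraries (12 C-to-T and 11 G-to-A positions against 10 A-to-G and 9 T-to-C). Runs of 5 lay at 2R from 6037885 to 6037899, 3R from 7577795 to 7577899, 3R from 11124625 to 11124652, 4 from 497291 to 497312 and X from 8916868 to 8916976.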
